A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

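The deposited processed values were used, which per the labels are log2 ratios between the mutant and the wild-type channel. Whether they were on that scale was tested on the spacing of the values. Under base 2, and with the sign in which Cy5 stands over Cy3 before turning, 100% of the gaps between ratios were whole multiples of 1 step within a tolerance of 0.02, against at most 13.3% for natural logarithms. The arrays with the mutant in Cy3 had thus been turned by the authors, and all values stand as log2(mutant / wild type). No further normalization was applied, since array medians lay near 0. No array pair held identical values. Of 6267 ORFs, 5856 had a name in the reference table of yeast genes and 411 had none. The table served for gene names and for the order of genes along chromosomes. The array design names no genome build, so distances in bases were not used here, and places were counted as genes from the chromosome end.

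The choices below were made before the data were examined, except where stated. ORFs with values on at least 3 of 4 arrays in each group were tested, which left 4554, of which 4520 had a place on a chromosome, and set aside 1713, of which 406 had no value at all. A linear model with a mean for each group and 1 common term for dye orientation was fitted with limma (lmFit and eBayes). The prior had 5.48 degrees of freedom, and a complete gene had 5 residual degrees of freedom. Each group mean was tested against 0 and the groups against each other, with Benjamini-Hochberg adjustment over all genes and a limit of 0.05. The wild type has no sample of its own, so its own spread is not in these tests.

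The 29 gene lists were the deleted genes, silent mating cassettes, a-specific, alpha-specific and haploid-specific genes, pheromone response, galactose genes, phosphate starvation, iron regulon, thiamine and vitamin B6 genes, ribosome biogenesis, general stress response, heat shock chaperones, respiration, glycolysis, hexose transporters, early meiosis, amino acid synthesis under Gcn4, methionine and sulphate, purine synthesis, auxotrophic markers, core histones, members of the Set2 and Sir pathways, genes with known cryptic internal start sites, ribosomal proteins, the COS family, the PAU, DAN and TIR family, the YRF1 helicase family, and the subtelomeric genes. The last were the 15 outermost protein-coding genes of each chromosome end. Ribosomal proteins were collected by name, which also took in RPP1, an RNase P subunit. The 27 lists with at least 3 tested genes were tested with cameraPR at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison, and again with the correlation estimated from the genes with complete values and with fry. The shares of called genes near the ends were compared with Fisher's exact test. Chromosome medians were tested by exact sign-flip permutation.

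Genes were named by a rule. For each comparison these were the 10 highest and 10 lowest log2 ratios past the test whose arrays all had the same sign, or for the difference between the groups whose arrays did not overlap. SET2, SIR4, the cassettes and the cell-type genes were always looked at, and from each other list up to 4 members with the smallest p, or 10 for the subtelomeric genes. Genes named outside the rule, DAL1, MPH2, RIB4, ENO1 and PGK1, the genes with opposite calls and those in the closing observations among them, were chosen after their values were seen.

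Recovery was measured on 20 simulated data sets of 4554 genes with the residual spread and dye effects of the fitted model and the missing values of the real arrays. Both groups had the same spread and the same dye effect for a gene. On the real arrays the SD of the difference between orientations was 0.583 in set2Δ and 0.252 in set2Δsir4Δ. The shares below therefore do not measure false or missed calls from that larger difference in set2Δ. The noise was drawn independently for each gene. Effects of 1.25-fold were called in 26.6% of cases in set2Δ and 11.2% in the difference between the groups, of 1.5-fold in 90.6% and 63.4%, and of 2-fold in 100% and 98.0%. Of all calls, 6.01% in set2Δ, 5.24% on the set2Δsir4Δ arrays and 4.51% in the difference were false. A shift of 0.4 given to a list of 30 genes in the set2Δsir4Δ group was called in 20 of 20 data sets, and an unshifted list in 0. These list calls used an unadjusted p under 0.05 and genes without correlation. They therefore do not measure false list calls among correlated genes.

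Alternatives were centred arrays, centred and scaled arrays, quantile normalization, no dye term, array weights, robust fitting, no filter on missing values, complete genes only, each mutant alone, a block for replicate number, stricter limits, and each array left out. Other widths of the subtelomeric list and the list without multigene families were also run. A dye term for each group, the 5 outermost genes and removal of the mating lists were chosen after seeing the data. A definition of subtelomeric genes by 30 kb was not run, since it needs coordinates on a named build. Raw intensities were not analysed here. R 4.3.3 with limma 3.58.1 and jsonlite 2.0.0 and Python 3.11.15 with matplotlib 3.10.9 were used.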

Results

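Budding yeast lacking SET2, which encodes the histone H3 lysine methyltransferase that travels with elongating RNA polymerase II, was compared with wild type on ORF microarrays, and so was a strain labelled as lacking both SET2 and SIR4. Sir4 is a subunit of the Sir silencing complex, which represses the silent mating cassettes and genes next to telomeres. Each strain was hybridised on 4 arrays against wild-type RNA carrying the other dye, with the mutant in Cy3 on 2 arrays and in Cy5 on the other 2. Cells had been grown to log phase at 30 °C in rich medium with added adenine. Of 6267 ORFs, 4554 had enough values to be tested and 3426 had a value on all 8 arrays. The arrays held 4613 to 4926 values in the set2Δ group and 4846 to 5577 in the set2Δsir4Δ group, with medians between -0.09 and 0.05 on the log2 scale. Values below are log2(mutant / wild type) ± SE, with n = 4 arrays unless another n or SD is given. The SE comes from the linear model with its dye term. It pools the spread over both groups and is moderated across genes, so it is not the spread over those 4 arrays alone. The labels do not say whether the arrays came from separate cultures or shared 1 wild-type RNA, so p-values measure only the spread between these arrays, which may be technical. Spot intensities were not used here, and the number of arrays limits the precision.

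The deleted genes were read first as a check on the labels. The SET2 spot had a value on 2 of the set2Δ arrays, at -2.61 and -3.24, and averaged -1.69 ± 0.19 (SD, n = 4) on the set2Δsir4Δ arrays. The SIR4 spot had no value on the set2Δ arrays and averaged -0.07 ± 0.14 (SD, n = 4) on the arrays labelled set2Δsir4Δ, so it did not bear out the deletion named in the label. The part of each gene that its spot covers is not given in the sources used here, and a spot outside the deleted part would check nothing. The name set2Δsir4Δ is therefore used below only as the label of those arrays.

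In set2Δ cells, genes of the general stress response and heat shock chaperones were higher than in wild type. Respiration genes were also higher, and genes of ribosome biogenesis, phosphate starvation and the PAU, DAN and TIR cell wall family lower, but these 4 lists did not pass with an estimated correlation (adjusted p = 0.056, 0.14, 0.056 and 0.18 with an estimated correlation), while all 4 passed with fry (adjusted p 0.0042 to 0.0045). The largest increases were in YNR064C (2.69 ± 0.12, n = 3), the putative transporter PUL3 (2.41 ± 0.12), the small heat shock protein HSP12 (2.37 ± 0.18, 5.17-fold), LYS2 of lysine synthesis (2.30 ± 0.22, n = 3) and the glucokinase GLK1 (2.02 ± 0.20). LYS2 is also on the list of auxotrophic markers, and whether the strains differ in this marker was not tested. Among the genes tested, the largest decreases were in COS10 (-2.16 ± 0.20, n = 3), YIL175W (-1.67 ± 0.08), AIF1, a mitochondrial cell death factor homologue (-1.58 ± 0.08), and DMC1, the meiotic recombinase (-1.52 ± 0.16, n = 3). In all, 537 of 4554 genes were higher and 593 lower at an adjusted p under 0.05, and 180 and 85 of them by at least 1.5-fold. Which direction had more calls depended on scaling, with 630 higher and 525 lower in centred arrays and 565 and 420 in centred and scaled arrays. Further large increases were in the secreted glycoprotein YGP1 (1.98 ± 0.11), YCL042W beside GLK1 (1.66 ± 0.16, n = 3), the oligopeptide transporter OPT2 (1.58 ± 0.12), the phosphoglucomutase PGM2 (1.49 ± 0.10) and the mitochondrial aldehyde dehydrogenase ALD4 (1.49 ± 0.16). Lower by over 2-fold were also the neighbours YDL038C (-1.19 ± 0.25) and PRM7 (-1.16 ± 0.16), YIR042C (-1.19 ± 0.12, n = 3), and the near-identical thiamine genes THI5, THI12 and THI11 (-1.15, -1.13 and -1.11, n = 3 each), whose spots can share signal.

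Of 26 general stress genes tested in set2Δ, 21 were higher and 0 lower, with a median of 0.84. The count adjusted over the list alone was also 21, and the set test gave an adjusted p of 1.1e-26, or 4.5e-06 with an estimated correlation. The trehalose synthase subunit TSL1 stood at 1.26 ± 0.12. Of 17 heat shock chaperones, 8 were higher and 1 lower (11 and 1 adjusted over the list alone), with a median of 0.26 and adjusted p = 0.00065, or 0.0072 with an estimated correlation. They included AHA1 (0.70 ± 0.11) and SSA1 (0.57 ± 0.10). Of 29 respiration genes, 18 were higher and 1 lower (24 and 1 adjusted over the list alone), with a median of 0.49, among them the succinate dehydrogenase subunit SDH2 (0.80 ± 0.11) and the citrate synthase CIT1 (0.77 ± 0.10). Their set test gave adjusted p = 2.8e-09 but adjusted p = 0.056 with an estimated correlation.

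Of 35 ribosome biogenesis genes, 23 were lower and 0 higher in set2Δ (25 and 0 adjusted over the list alone), with a median of -0.41. The set test gave adjusted p = 2.6e-09, and adjusted p = 0.14 with an estimated correlation. NSR1 (-0.76 ± 0.10), a nucleolar protein, and ERB1 (-0.71 ± 0.10) were among them. Of 12 phosphate starvation genes, 6 were lower and 0 higher (7 and 0 adjusted over the list alone), with a median of -0.34, adjusted p = 7.9e-05, and adjusted p = 0.056 with an estimated correlation. The phosphate transporter PHO89 was at -1.03 ± 0.11 (n = 3), and the acid phosphatases PHO12 and PHO11, which resemble each other, were at -0.97 and -0.85. Of 18 PAU, DAN and TIR genes, 10 were lower and 0 higher (13 lower and 1 higher adjusted over the list alone), with a median of -0.47, adjusted p = 7.4e-07, and adjusted p = 0.18 with an estimated correlation. PAU4 stood at -0.80 ± 0.11 and PAU2 at -0.71 ± 0.09.

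COS genes, a subtelomeric family of similar membrane proteins, were higher in 8 of 10 members and lower in 1 in set2Δ (the same counts adjusted over the list alone), with a median of 0.44 and adjusted p = 0.020. The call was lost with an estimated correlation (adjusted p = 0.29 with an estimated correlation), without set2Δ array 2 (adjusted p = 0.079) and without set2Δ array 4 (adjusted p = 0.089). COS6 was at 0.96 ± 0.18 and COS3 at 0.60 ± 0.10, against COS10 at -2.16. Among 6 genes known for cryptic internal start sites, which Set2 represses, 3 were higher and 0 lower, also adjusted over the list alone, with a median of 0.17 and adjusted p = 0.043. PCA1, a cadmium exporter, rose most (1.34 ± 0.12, n = 3). That call was lost with an estimated correlation (adjusted p = 0.16 with an estimated correlation), with no dye term (0.088), without set2Δ array 1 (0.063), array 2 (0.089) or array 4 (0.093), and without set2Δsir4Δ array 1 (0.052).

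The other 19 of the 27 lists did not pass the set test with cameraPR in set2Δ. With fry, galactose (adjusted p = 0.025), glycolysis (0.036), early meiosis (0.042) and Set2 and Sir pathway genes (0.041) passed in the same direction as with cameraPR. Thiamine and vitamin B6 genes (0.025, higher) and auxotrophic markers (0.044, lower) passed with fry in the direction opposite to that of cameraPR. Of 10 core histone genes none was called by limma, and 0 had an unadjusted p under 0.05. Of 111 ribosomal protein genes 3 were higher and 5 lower, and 0 adjusted over the list alone with limma, where 5 higher and 19 lower had an unadjusted p under 0.05. None of 3 silent cassette genes was called or had an unadjusted p under 0.05. Of 6 a-specific genes 0 were higher and 2 lower (AGA2, -0.79 ± 0.11, and ASG7, -0.50 ± 0.09), of 10 haploid-specific genes 0 and 1, and of 12 pheromone response genes 2 and 1 (3 and 2 adjusted over the list alone). Of 7 galactose genes 2 were higher and 1 lower, of 14 thiamine and vitamin B6 genes 2 and 5, of 12 early meiosis genes 1 and 3, and of 10 hexose transporters 2 and 3 (2 and 4 adjusted over the list alone). SNZ1, of vitamin B6 synthesis, rose by 1.34 ± 0.08, and the transporters HXT7 and HXT16 stood at 1.39 ± 0.19 and -1.07 ± 0.09. Of 28 amino acid synthesis genes 2 were higher and 4 lower, of 18 methionine and sulphate genes 3 and 2, of 12 purine genes 1 and 2, and of 5 auxotrophic markers 1 and 2 (2 and 2 adjusted over the list alone). Among 16 Set2 and Sir pathway genes, SAS4 of the SAS acetyltransferase was higher (0.80 ± 0.11) and 1 was lower. YRF1 helicase genes gave 0 calls of 3 with limma over all genes, with 2 higher adjusted over the list alone and 2 at an unadjusted p under 0.05. Glycolysis genes (4 higher, 0 lower of 9, and 6 and 0 adjusted over the list alone) passed without set2Δ array 1 (adjusted p = 0.0074), against 0.069 with all arrays. Iron genes (3 higher, 0 lower of 11) passed without set2Δ array 2 (adjusted p = 0.044) or set2Δsir4Δ array 3 (0.033), against 0.070. The alpha-specific genes MF(ALPHA)2 (0.66 ± 0.12, n = 3) and SAG1 (0.52 ± 0.11) were higher, the first not without set2Δ array 4 (adjusted p = 0.064).

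The set2Δ arrays differed by dye. Pairs of equal orientation correlated across genes at 0.68 to 0.76, and pairs of opposite orientation at -0.09 to 0.31, against 0.86 to 0.90 and 0.69 to 0.80 on the set2Δsir4Δ arrays. Across genes the SD of the difference between orientations was 0.583 in set2Δ and 0.252 in set2Δsir4Δ. The 1130 calls in set2Δ fell to 459 without set2Δ array 4 and to 713 with no dye term, and all 713 were among the 1130.

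On the arrays labelled set2Δsir4Δ, the genes that make a haploid cell of mating type a able to mate were lower by up to 82.3-fold than in wild type. The a-factor gene MFA2 was at -6.36 ± 0.23 (n = 3), BAR1, the protease that degrades alpha-factor, at -5.76 ± 0.10 (54.2-fold) and STE2, the alpha-factor receptor, at -5.47 ± 0.14 (44.4-fold). The MAP kinase FUS3 (-4.31 ± 0.25), the G protein subunits GPA1 (-4.11 ± 0.12, n = 3) and STE4 (-3.85 ± 0.10), the adhesin subunit AGA2 (-3.77 ± 0.11), the a-factor exporter STE6 (-3.29 ± 0.10), the arrest factor FAR1 (-2.71 ± 0.13) and the end-joining factor NEJ1 (-2.54 ± 0.09) followed. Stress genes, chaperones and COS genes were higher. In all, 503 genes were higher and 644 lower, and 216 and 187 of them by at least 1.5-fold, against 581 and 572 in centred arrays and 801 and 759 in centred and scaled arrays.

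All 6 a-specific genes tested were lower (median -4.62, adjusted p = 1.9e-122), as were all 10 haploid-specific genes (median -2.18, adjusted p = 4.3e-58), both also adjusted over the list alone and with an estimated correlation. Of 12 pheromone response genes, 8 were lower and 0 higher (10 and 0 adjusted over the list alone), with adjusted p = 2.7e-09, and adjusted p = 3.9e-06 with an estimated correlation. They included AGA1 (-2.07 ± 0.14), the transcription factor KAR4 (-1.99 ± 0.16) and the signalling regulator SST2 (-1.57 ± 0.11). All 3 tested genes of the mating cassettes were higher, also adjusted over the list alone, with HMLALPHA2 at 0.74 ± 0.14, MATALPHA2 at 0.70 ± 0.13 and HMRA2 at 0.55 ± 0.12. The α2 and a2 sequences at MAT and the silent loci share sequence, so these spots cannot be told apart by locus. Their set test gave adjusted p = 0.023, lost with an estimated correlation (adjusted p = 0.16 with an estimated correlation) and without set2Δsir4Δ array 2 (adjusted p = 0.056). HMLALPHA1 and MATALPHA1, measured too rarely in set2Δ to be tested there, averaged 0.82 ± 0.20 and 1.19 ± 0.44 (SD, n = 4). The alpha-specific STE3, which encodes the a-factor receptor and had no value in set2Δ, averaged -1.06 ± 0.57 (SD, n = 3) and was called lower with these arrays fitted alone. The alpha-specific MF(ALPHA)2 was at 0.40 ± 0.10, called but not without set2Δsir4Δ array 1 (adjusted p = 0.092) or array 3 (0.063), and SAG1 was at 0.31 ± 0.11 (adjusted p = 0.051).

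**Figure D1:**
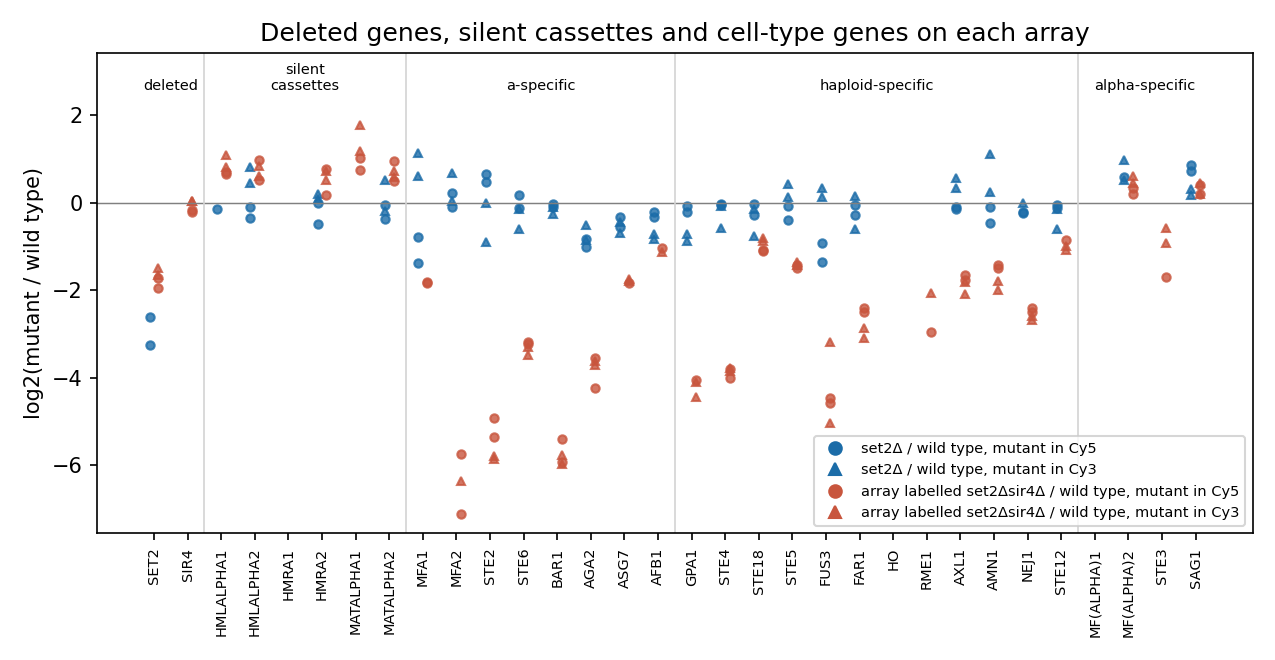
Log2(mutant / wild type) on each array for the deleted genes, the silent cassettes and the cell-type-specific genes (vertical axis, log2; 1 marker per array, colours give the group, shapes the dye of the mutant). MFA2, BAR1 and STE2 lie below -4.9 on every set2Δsir4Δ array that measured them, and SIR4 lies between -0.21 and 0.05.

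Outside the mating genes, and among genes with enough values in both groups to be tested, the largest increases on the set2Δsir4Δ arrays were in HPF1 (2.76 ± 0.26) and CSS1 (2.36 ± 0.24), which encode related cell wall proteins, HSP12 (2.27 ± 0.18), YNR064C (2.13 ± 0.10), OPT2 (1.91 ± 0.14, n = 3), PUL3 (1.88 ± 0.14, n = 3), TSL1 (1.84 ± 0.12), PGM2 (1.73 ± 0.12, n = 3), YGP1 (1.70 ± 0.11) and YMR090W (1.59 ± 0.15). Of 26 general stress genes 21 were higher and 1 lower, also adjusted over the list alone, with a median of 0.98, adjusted p = 4.0e-20, and adjusted p = 3.3e-05 with an estimated correlation. Of 17 chaperones 15 were higher and 0 lower (16 and 1 adjusted over the list alone), with a median of 0.64, adjusted p = 1.2e-09, and adjusted p = 7.0e-08 with an estimated correlation. STI1 stood at 0.90 ± 0.10 and AHA1 at 0.84 ± 0.11. Of 10 COS genes 9 were higher and 0 lower (9 and 1 adjusted over the list alone), with a median of 1.28, adjusted p = 1.0e-14, and adjusted p = 5.8e-06 with an estimated correlation. COS2 (1.35 ± 0.11) and COS1 (1.35 ± 0.09) may share signal with other members. The 3 YRF1 helicase genes tested were all higher, also adjusted over the list alone (median 0.82, adjusted p = 0.0052), and too few had complete values for an estimated correlation. YRF1-2 was not called without set2Δsir4Δ array 1 (adjusted p = 0.051) or array 2 (0.15).

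Respiration genes were higher in 18 of 29 and lower in 1 on the set2Δsir4Δ arrays (19 and 1 adjusted over the list alone), with a median of 0.38, adjusted p = 1.9e-06, and adjusted p = 0.089 with an estimated correlation. CIT1 was at 0.93 ± 0.10. Ribosome biogenesis genes were lower in 22 of 35 and higher in 0 (25 and 0 adjusted over the list alone), with a median of -0.42, adjusted p = 1.4e-07, and adjusted p = 0.13 with an estimated correlation. NSR1 was at -1.03 ± 0.10 and the helicase DBP2 at -1.01 ± 0.11. Phosphate genes were lower in 4 of 12 and higher in 0, also adjusted over the list alone, with a median of -0.18, adjusted p = 0.0027, and adjusted p = 0.12 with an estimated correlation. PHO11 and PHO12 were at -1.19 ± 0.08 and -1.15 ± 0.09. Thiamine and vitamin B6 genes were lower in 6 of 14 and higher in 2 (8 and 2 adjusted over the list alone), with a median of -0.35, adjusted p = 0.00053, and adjusted p = 0.066 with an estimated correlation. SNZ3 (-1.54 ± 0.10), SNZ2 (-1.52 ± 0.11, n = 3) and SNO2 (-1.35 ± 0.08) lie in duplicated subtelomeric blocks, and SNZ1 went the other way (1.02 ± 0.08).

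The remaining lists did not pass with cameraPR on the set2Δsir4Δ arrays, though the purine list passed with fry (adjusted p = 0.0020). Core histones had 0 higher and 1 lower of 10 (0 adjusted over the list alone), the list of ribosomal proteins 1 and 1 of 111 (0 adjusted over the list alone with limma, 3 and 2 at an unadjusted p under 0.05), PAU, DAN and TIR genes 0 and 2 of 18 (0 and 1 adjusted over the list alone), and Set2 and Sir pathway genes 1 (SAS4, 0.75 ± 0.11) and 2 of 16. The lower pathway genes were SAS5 (-0.52 ± 0.09) and SIR2 (-0.47 ± 0.10), the latter not called without set2Δsir4Δ array 1 (adjusted p = 0.054). In the list of ribosomal proteins the lower gene was RPP1 (-0.37 ± 0.10), an RNase P subunit taken in by its name, so no ribosomal protein gene was called lower. RPP1 lost its call without set2Δsir4Δ array 1 (adjusted p = 0.091), 2 (0.092) or 4 (0.088), and the higher gene, RPS22B (0.53 ± 0.12), without array 1 (0.058) or 4 (0.058). Genes with cryptic start sites had 3 higher and 0 lower of 6 (adjusted p = 0.32). Galactose genes had 0 higher and 3 lower of 7, iron genes 3 and 1 of 11, early meiosis genes 2 and 3 of 12 (3 and 3 adjusted over the list alone), amino acid genes 4 and 5 of 28, methionine and sulphate genes 4 and 2 of 18, purine genes 2 and 5 of 12 and auxotrophic markers 2 and 1 of 5, where LYS2 was at 1.59 ± 0.19. No glycolysis gene of 9 was called by limma, and 3 higher and 1 lower had an unadjusted p under 0.05. Of 5 further glycolysis genes with too few values in set2Δ, 4 were called higher with these arrays fitted alone, with ENO1 at 0.48 ± 0.07 and PGK1 at 0.36 ± 0.06. That separate fit called 230 of all 915 such ORFs higher, and its calls are not comparable with those for the 9 genes. Hexose transporters had 0 higher and 4 lower of 10 (0 and 5 adjusted over the list alone, adjusted p = 0.11), and passed without set2Δsir4Δ array 4 (adjusted p = 0.038). The 1147 calls fell to 596 without set2Δsir4Δ array 1 and 758 without array 4. They were 2156 when these 4 arrays were fitted alone and 1844 with array weights.

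In the difference between the arrays labelled set2Δsir4Δ and the set2Δ arrays the mating genes came first, with MFA2 at -6.59 ± 0.30, BAR1 at -5.65 ± 0.14, STE2 at -5.53 ± 0.19 and FUS3 at -3.87 ± 0.35. Some genes in this difference had values on only 3 arrays in a group, which is not marked for each gene. Among them were MFA2, GPA1, NEJ1, GIT1, YIR042C, COS10, YEL073C, YIL175W, GAL7 and STE12. STE4 (-3.67 ± 0.15), GPA1 (-3.65 ± 0.16), STE6 (-3.13 ± 0.14), AGA2 (-2.98 ± 0.16), FAR1 (-2.52 ± 0.18) and NEJ1 (-2.39 ± 0.14) came next. The largest increases were all in genes near chromosome ends or, for YIL175W, without a place in the reference order. They were the glycerophosphoinositol permease GIT1 (2.14 ± 0.16), YIR042C (1.88 ± 0.15), AIF1 (1.77 ± 0.12), COS10 (1.73 ± 0.27), the transcription factor RDS1 (1.68 ± 0.13), the aspartic protease YPS6 (1.65 ± 0.19), YEL073C (1.45 ± 0.16), YIL175W (1.39 ± 0.13), YHR214W (1.38 ± 0.18) and YAR068W (1.34 ± 0.25, not called without set2Δsir4Δ array 4, adjusted p = 0.057). In all, 38 genes were higher and 74 lower, so 33.9% of the calls were higher, against 82 and 102 (44.6%) with arrays centred and scaled and 69 and 83 (45.4%) with quantile normalization. The 112 calls became 74 without set2Δ array 4, 64 without set2Δsir4Δ array 1 and 70 without set2Δsir4Δ array 4, and 168 without set2Δ array 3.

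All 6 a-specific genes were lower in this difference (median -4.33), as were 9 of 10 haploid-specific genes (10 adjusted over the list alone, median -2.19) and 6 of 12 pheromone response genes (9 adjusted over the list alone, median -0.69), with 0 higher in each. The pheromone list gave adjusted p = 1.3e-13, and all 3 lists passed with an estimated correlation. AGA1 was at -2.19 ± 0.20, the fusion gene FIG1 at -1.79 ± 0.22, PRM5 at -1.55 ± 0.17 and SST2 at -1.42 ± 0.16. The haploid-specific STE12 (-0.70 ± 0.15, 3 arrays in the set2Δsir4Δ group) lost its call without set2Δ array 2 or 4 or any set2Δsir4Δ array, at adjusted p between 0.050 and 0.16. COS genes were higher in 7 of 10 and lower in 0 (8 and 0 adjusted over the list alone), with a median of 0.73, adjusted p = 2.8e-11, and adjusted p = 0.00015 with an estimated correlation. Chaperones had a median of 0.29 (adjusted p = 0.00019, and 0.0012 with an estimated correlation), with 1 of 17 called, also adjusted over the list alone, which was STI1 at 0.66 ± 0.14. Every array left out except set2Δ array 3 and set2Δsir4Δ array 3 ended the call of STI1 (adjusted p 0.064 to 0.13). Galactose genes were lower in 2 of 7, also adjusted over the list alone (GAL10, -1.21 ± 0.19, and GAL7, -0.81 ± 0.14, 3 arrays in the set2Δsir4Δ group), with a median of -0.24, adjusted p = 0.021, and 0.026 with an estimated correlation. The list did not pass without set2Δ array 3 (adjusted p = 0.092) or set2Δsir4Δ array 3 (0.11), and GAL7 was not called without set2Δ array 4 (0.058), set2Δsir4Δ array 3 (0.11) or set2Δsir4Δ array 4 (0.064).

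PAU, DAN and TIR genes had a median difference of 0.40, with 1 higher and 0 lower of 18 over all genes and 11 and 0 adjusted over the list alone. Their set test gave adjusted p = 1.4e-05, and adjusted p = 0.21 with an estimated correlation. Thiamine and vitamin B6 genes had 2 higher and 5 lower of 14 (3 and 6 adjusted over the list alone), with a median of -0.14, adjusted p = 0.0017, and adjusted p = 0.098 with an estimated correlation. SNZ3 (-1.47 ± 0.14), SNO3 (-1.34 ± 0.15), SNO2 (-1.30 ± 0.12) and SNZ2 (-1.24 ± 0.14) were lower, and the list did not pass without set2Δ array 3 (adjusted p = 0.073). The 3 cassette genes had a median of 0.59, with 0 called by limma over all genes, 3 higher at an unadjusted p under 0.05 and 3 higher adjusted over the list alone. The cassette list gave adjusted p = 0.015, lost with an estimated correlation (adjusted p = 0.14 with an estimated correlation), without set2Δ array 3 (0.051) and without set2Δsir4Δ array 2 (0.060). YRF1 genes had 1 higher of 3, also adjusted over the list alone (median 0.57, adjusted p = 0.031), and did not pass with no dye term (0.097), without set2Δ array 2 (0.11) or 3 (0.17), or without set2Δsir4Δ array 2 (0.14). The called gene, YRF1-4 (0.59 ± 0.13, 3 arrays in the set2Δsir4Δ group), lost its call with each of the 8 arrays left out (adjusted p 0.054 to 0.19), and PAU2 (0.60 ± 0.12), the called PAU gene, with each but set2Δ array 1 (0.051 to 0.13). The general stress list (0 higher and 1 lower of 26, 4 and 1 adjusted over the list alone, median 0.03) and the ribosome biogenesis list (0 called of 35 by limma, 1 higher and 2 lower at an unadjusted p under 0.05, median -0.08) did not pass, with adjusted p = 0.48 and 0.63. The lower stress gene was HSP26, a small heat shock protein (-1.50 ± 0.24). Of 6 genes with cryptic start sites only PCA1 was called over all genes (-0.94 ± 0.16), with 2 lower adjusted over the list alone, and it was not called without set2Δ array 4 (adjusted p = 0.12) or set2Δsir4Δ array 1 (0.057). FIT2 of the iron list (-0.76 ± 0.17, 1 of 11) was called lower, but not without set2Δ array 2 or 4 or any set2Δsir4Δ array (adjusted p 0.084 to 0.11). ARG4 of the amino acid list (-0.55 ± 0.12, 1 of 28) was called lower, and lost its call with each array left out except set2Δ array 3 (adjusted p 0.067 to 0.14). No gene of 11 further lists was called by limma over all genes, and adjusted over the list alone 2 hexose transporters were higher and 2 lower, 2 purine genes lower and 1 glycolysis gene lower. At an unadjusted p under 0.05 they held, higher and lower, 1 and 1 phosphate genes, 0 and 1 respiration genes, 0 and 2 glycolysis genes, 2 and 4 hexose transporters, 1 and 0 early meiosis genes, 1 and 0 methionine genes, 0 and 3 purine genes, 1 and 1 auxotrophic markers, 0 and 1 core histones, 0 and 1 pathway genes, and 6 and 3 ribosomal protein genes. The purine list did not pass with cameraPR (adjusted p = 0.24) but passed with fry (adjusted p = 0.044).

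Silencing by Sir proteins acts near chromosome ends, so genes were ordered from each end by their place in the reference. The 5 outermost genes of each end (96 tested) had medians of 0.09 in set2Δ, 0.58 on the set2Δsir4Δ arrays and 0.48 in the difference, against -0.02, -0.04 and -0.02 for the 3343 genes beyond place 50. Of the 96, 21 were higher and 22 lower in set2Δ, 58 and 6 on the set2Δsir4Δ arrays, and 21 and 2 in the difference. Genes at places 6 to 10 had medians of -0.02, 0.08 and 0.11, and genes at places 11 to 15 medians of 0.11, 0.06 and -0.06.

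**Figure D2:**
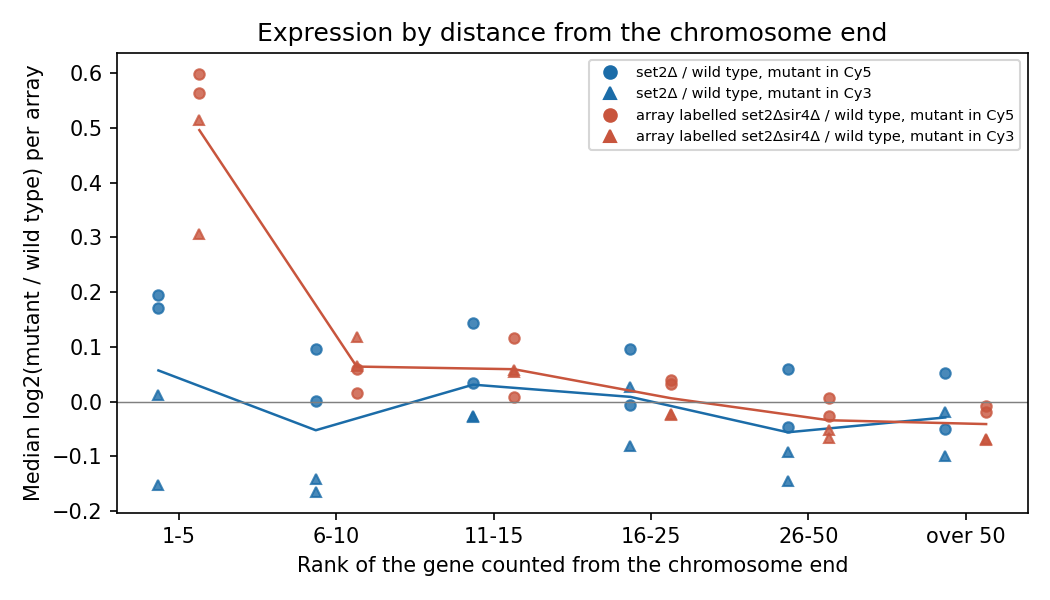
Median log2(mutant / wild type) per array (vertical axis, log2) of genes grouped by their rank from the chromosome end (horizontal axis); 1 marker per array, colours give the group and shapes the dye of the mutant. The set2Δsir4Δ arrays lie above the set2Δ arrays of the same dye at ranks 1 to 5, where the mean medians are 0.58 against 0.18 with the mutant in Cy5 and 0.41 against -0.07 in Cy3.

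Over the 15 outermost genes of each end, the list fixed before the data were examined, 111 of 328 were higher (121 adjusted over the list alone) and 40 lower (43) on the set2Δsir4Δ arrays. The higher share was 33.8% against 9.14% elsewhere (odds ratio 5.08, two-sided Fisher's exact test p = 1.5e-31). Their median lay 0.16 above that of other genes, and the set test over all lists gave adjusted p = 0.00014, and adjusted p = 0.044 with an estimated correlation. In set2Δ both directions were more frequent than elsewhere, with 66 higher (20.1%, odds ratio 2.03, exact p = 4.4e-06) and 57 lower (17.4% against 12.6%, odds ratio 1.45, exact p = 0.017), or 72 and 63 adjusted over the list alone. The set2Δ shift of 0.04 did not pass (adjusted p = 0.65). Among the subtelomeric genes in set2Δ were the hexokinase HXK1 (1.31 ± 0.12), DFP4 (-0.99 ± 0.10), HXT16 and PHO12. In the difference 27 were higher (50 adjusted over the list alone) and 11 lower (14), with a higher share of 8.23% against 0.215% elsewhere (odds ratio 41.6, exact p = 3.2e-24) and a shift of 0.13 (adjusted p = 6.5e-05, and 0.027 with an estimated correlation). The 11 lower ones included STE6, SST2, SNO2 and SNZ3. Fisher's test treats genes as independent, but the subtelomeric genes were correlated across arrays (estimated correlation 0.0314). Its p-values therefore do not measure the spread between arrays.

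Genes lower in set2Δ were followed into the difference between the groups. Of 593 genes lower in set2Δ, 14 were higher in the difference, which were GIT1, YIR042C, AIF1, COS10, RDS1, YPS6, YEL073C, YIL175W, DAL1, THI11, THI12, MPH2, RIB4 and PAU2. GIT1 was at -0.55 ± 0.12 (n = 3) in set2Δ and 1.59 ± 0.10 on the set2Δsir4Δ arrays, and AIF1 at -1.58 ± 0.08 and 0.19 ± 0.08. Of the 57 lower genes among the 15 outermost, 11 were in this group (19.3%), against 0.560% of the other 536 (odds ratio 41.8, two-sided Fisher's exact test p = 7.4e-10). Over all tested genes the odds ratio for a higher difference near the ends was 41.6, so the contrast was not particular to genes lower in set2Δ. The exact test here also treats genes as independent. Of 537 genes higher in set2Δ, 19 were lower in the difference. In 50 simulations with equal groups, at most 1 gene came out in either direction. Both contrasts hold the same set2Δ arrays, and with genes chosen on set2Δ arrays 1 and 3 and tested on arrays 2 and 4, or the reverse, 5 of 65 and 5 of 370 lower genes were called higher. The 14 became 8 without set2Δ array 2, 29 without array 3 and 6 without array 4, and 8 and 9 without set2Δsir4Δ arrays 1 and 4. The 19 became 11, 43 and 6 without the same set2Δ arrays, and 5, 8 and 8 without set2Δsir4Δ arrays 1, 3 and 4.

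**Figure D3:**
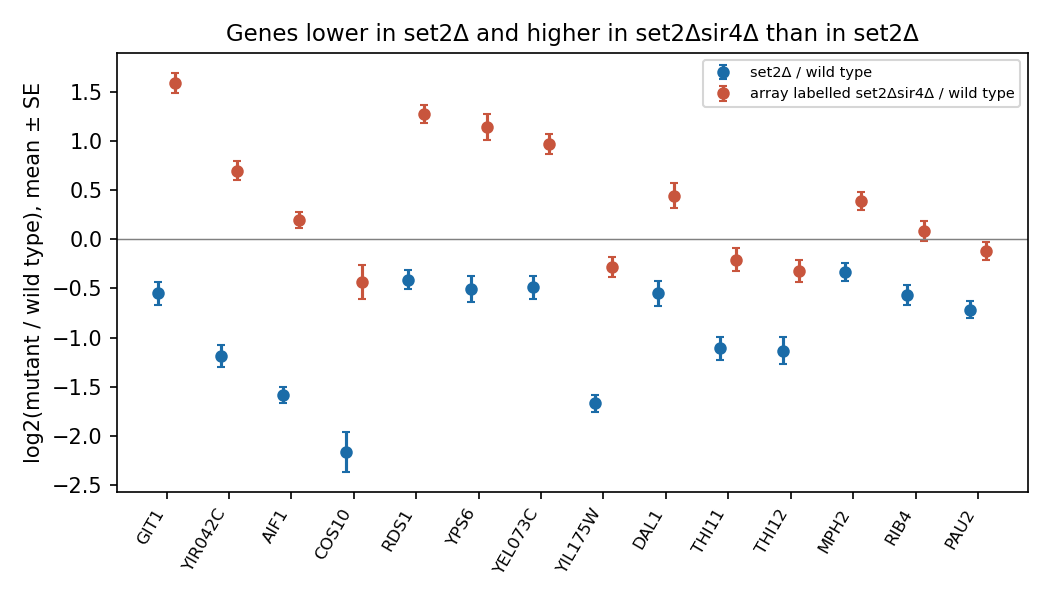
Log2(mutant / wild type), mean ± SE of the linear model (vertical axis), in set2Δ and on the arrays labelled set2Δsir4Δ for the 14 genes lower in set2Δ and higher in the difference between the groups. COS10 rises from -2.16 to -0.43 and GIT1 from -0.55 to 1.59.

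Of 593 genes lower in set2Δ and 644 lower on the set2Δsir4Δ arrays, 312 were shared (83.9 for independent lists), and of 537 and 503 higher genes 291 were shared (59.3 for independent lists). Opposite calls were made for 15 genes, among them GIT1, RDS1, YPS6, GAL7, GAL10 and FIG1. In set2Δ, FIG1 lost its call without set2Δ array 2 (adjusted p = 0.11), 3 (0.082) or 4 (0.18) or set2Δsir4Δ array 1 (0.050), and GAL7 without set2Δ array 4 (0.095). On the set2Δsir4Δ arrays GAL7 lost it without array 3 (0.17) or 4 (0.074), and GAL10 without array 1 (0.054) or 4 (0.053). Across the 4554 genes, which are not independent replicates, the mean log2 ratios correlated with Pearson's r = 0.562 (jackknife SE over arrays 0.108) and Spearman's rho = 0.622, and 71.7% had the same sign. The covariance was 0.0756. In 50 simulations without effects r averaged -0.0022, with a largest size of 0.0417, the covariance averaged -3.15e-05 and 0 calls were shared. The simulation drew separate wild-type noise for each array, and part of the observed value may come from wild-type RNA if the arrays shared it.

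**Figure D4:**
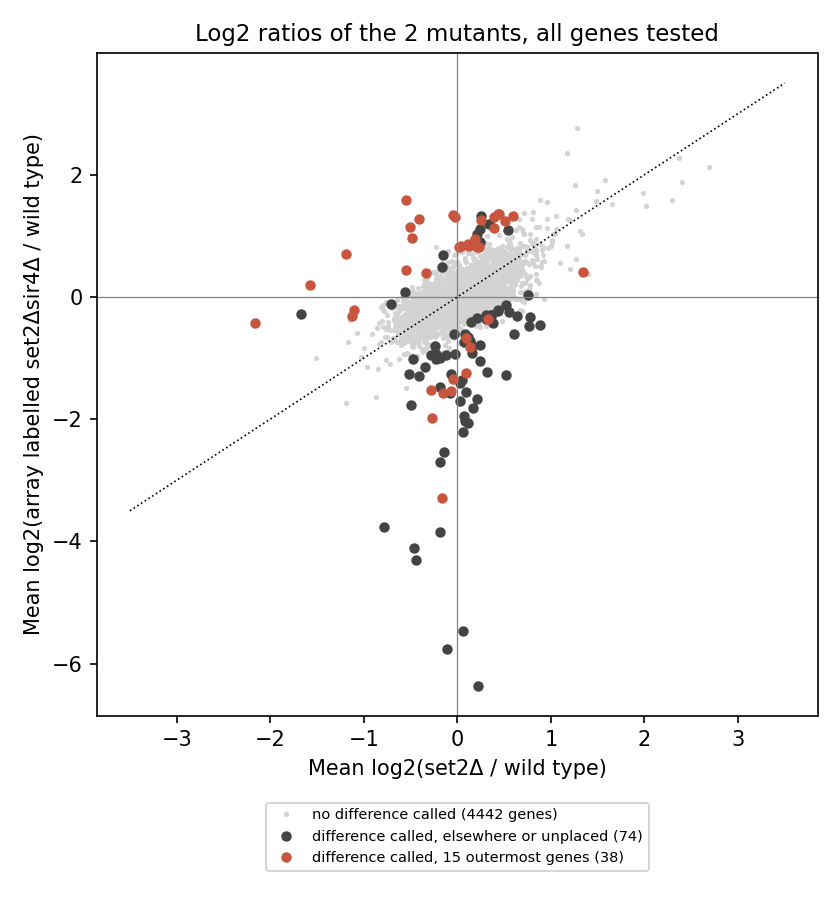
Mean log2(mutant / wild type) of each tested gene in set2Δ (horizontal axis) and on the arrays labelled set2Δsir4Δ (vertical axis), with the diagonal dotted; genes with a called difference between the groups are dark, or red if among the 15 outermost of an end. The log2 ratios of the 4554 genes correlate at r = 0.562, MFA2, BAR1 and STE2 lie furthest below the diagonal, and 27 of the 38 genes called higher are red.

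A change in the copy number of a whole chromosome would move the median of its genes. Chromosome medians averaged between -0.11 (chromosome I in set2Δ, SD 0.16) and 0.09 (chromosome II in set2Δ, SD 0.15). On the set2Δsir4Δ arrays the medians of chromosomes II, VIII, IX, X, XIII, XIV and XV lay below 0 on all 4 arrays, at -0.05 ± 0.02 (SD, n = 4) for XIV and -0.05 ± 0.01 (SD, n = 4) for XV, where the whole arrays had medians of -0.02 to -0.01. An exact sign-flip permutation of 4 arrays cannot give a two-sided p below 0.05 and decided nothing. An extra copy in every haploid cell would move a median by about 1, and no chromosome median passed 0.31 in size on any array.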

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

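Single arrays stood apart from the other 3 of their group in 21 of 447 groups of 4 values tested with Dixon's ratio, where about 22 would be met by chance at 1 in 20. Array 1 labelled set2Δsir4Δ had the larger spread of all values (SD 0.49 against 0.44 to 0.45, ratio 0.867). The median of respiration genes was 0.61 on set2Δ array 2 against 0.31 to 0.35 (ratio 0.862), and that of COS genes was 1.12 on set2Δsir4Δ array 4 against 1.28 to 1.29 (ratio 0.963). HSP26 was lower on set2Δ array 4 than on the others, which gave 0.14 to 0.28 (ratio 0.890), and HOP1, a meiotic chromosome protein, at -0.71 on set2Δ array 3 against 0.14 to 0.30 (ratio 0.843). On set2Δ array 1 STE12 (0.865), DBP2 (0.852) and ADE13 (0.854) were lower than on the others, and HIS3 (0.837) and PRM5 (0.922) higher. STE4 (0.893) was lower and MET1 (0.876) higher on set2Δ array 2, and AHA1 (0.878) lower and NSR1 (0.943) higher on set2Δ array 4. Among the set2Δsir4Δ arrays, ADE17 (0.931) and HSP10 (0.877) were lower and PAU5 (0.849) higher on array 1. YPS6 (0.839) was lower and ATP3 (0.843) higher on array 3, and YEL073C (0.851) lower and SNZ3 (0.861) higher on array 4. All arrays were kept. Outside the comparisons, 401 of 915 ORFs with too few values in set2Δ were called on the set2Δsir4Δ arrays alone.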

How the results depend on the processing

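The 1130 calls in set2Δ (537 higher, 593 lower) became 713 with no dye term (354 lower), 475 at an adjusted p under 0.01 (239 and 236), 265 at 1.5-fold or more (180 and 85) and 1728 with a dye term per group (841 higher), and 459 to 1317 with 1 array left out (251 to 604 and 208 to 713). The 1147 calls on the set2Δsir4Δ arrays became 1844 with array weights (806 and 1038), 623 at an adjusted p under 0.01 (286 and 337), 403 at 1.5-fold (216 and 187), 2156 fitted alone (944 and 1212) and 596 to 1288 with 1 array left out (278 to 559 and 318 to 729), with 801 higher when centred and scaled. The 112 differences became 184 when centred and scaled (82 higher), 61 at an adjusted p under 0.01 (15 and 46), 274 with a dye term per group (108 and 166) and 64 to 168 with 1 array left out (16 to 64 and 48 to 104); 25 were higher with no dye term, 69 with quantile normalization and 67 with array weights. The 14 genes lower in set2Δ and higher in the difference became 23 with no filter, 25 with weights, 4 at 0.01, 7 at 1.5-fold, 47 with a dye term per group, 5 and 5 when chosen on separate arrays and 6 to 29 with 1 array left out. The 19 in the other direction became 9 with no dye term, 2 at 0.01, 7 at 1.5-fold, 80 with a dye term per group, 2 and 3 when chosen on separate arrays and 5 to 43 with 1 array left out. With a block for replicate number, the counts were 613 (333 and 280), 763 (412 lower), 67 (17 higher), 5 and 6, but equal numbers did not pair arrays (r across genes 0.227, -0.164, 0.153 and -0.214). Lists past the test went from 8, 13 and 11 to 2, 7 and 7 with an estimated correlation, to 14 in set2Δ with fry, and to 6 to 9, 12 to 14 and 7 to 11 with 1 array left out, where 7 came without set2Δ array 3. Centring moved the set2Δsir4Δ medians of chromosomes IX, X, XIV and XV to -0.0034, 0.00522, -0.0361 and -0.0278. The subtelomeric shift ranged from 0.0192 to 0.0846, 0.142 to 0.195 and 0.113 to 0.158 with 1 array left out, and in the difference it was 0.22 over the 10 outermost genes, 0.07 over 25, 0.10 without multigene families and 0.50 over the 5 outermost. The agreement of the mutants ranged from 0.486 to 0.604 and was 0.647 without the mating lists. Of named genes, 64 of 93 calls in set2Δ, 77 of 101 on the set2Δsir4Δ arrays and 36 of 45 in the difference were kept with every array left out. The cause of these changes was not tested.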

Other observations

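Genes measured on the set2Δsir4Δ arrays but too rarely on the set2Δ arrays, named after their values were seen, could be compared only with wild type. Their SE comes from a fit of the set2Δsir4Δ arrays alone. COS12, the outermost gene of its end, was higher by 3.27 ± 0.07, and so were the ORFs YCL074W (2.95 ± 0.08, n = 3), YCL075W (2.28 ± 0.06) and YCL076W (1.83 ± 0.06), which lie near the silent cassette HML. YFL063W (2.04 ± 0.07), YNL337W (2.01 ± 0.06) and YAL069W (1.94 ± 0.07) followed. The transcription factor TEC1 was lower by -2.18 ± 0.07, as were the Ty1 ORFs YJR028W (-1.65 ± 0.08), YJR027W (-1.56 ± 0.07) and YMR045C (-1.43 ± 0.06), and the mRNA methyltransferase gene IME4 (-1.40 ± 0.11, n = 3). In all, 230 of 915 such ORFs were higher and 171 lower, and 477 had an unadjusted p under 0.05. Of 53 subtelomeric ones 20 were higher and 9 lower.

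For the genes nearest the chromosome ends, the set of 5 genes per end, the removal of the mating lists and the tests on dye and on single ends were chosen only after the result was seen. The median difference of 0.48 between the groups did not come from a dye effect, as it was at least 0.398 in either orientation. Without multigene families it was 0.460 over 49 of the 96 genes, so the named families alone did not carry it. Of those 49 genes 8 were called higher, against 21 of the 96. The families were picked by gene name, so any repeated ORF with only a systematic name stayed in. Shared signal between spots was thus not excluded. Removing the mating lists left 95 of the 96 genes (median 0.475), too small a change for that test to decide anything. A few ends did not carry the difference, since 28 of 31 ends lay above 0. A loss of Sir silencing at the ends is a hypothesis that these values leave open. Against wild type, a-specific and haploid-specific genes were also lower (medians -4.62 and -2.18) and cassette genes higher. The cassette list passed the set test against wild type at the preset correlation (adjusted p = 0.023) and with fry (0.0076), but not with an estimated correlation (adjusted p = 0.16). In the difference 0 of its 3 genes were called over all genes, and 3 were higher adjusted over the list alone. The SIR4 spot did not bear out the deletion, and without a sir4Δ strain dependence on SET2 was not tested. Over the 15 outermost genes, 2 of 35 splits of the arrays gave a shift as large (0.135, highest other 0.139), so chance was not excluded for that wider set.

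For stress and ribosome biogenesis genes, the test on the wild-type culture was chosen only after the result was seen. Stress genes stood above ribosome biogenesis genes on 8 of 8 arrays, which a dye effect would not give. Slower growth of both mutants and a wild-type culture in another state could not be told apart, as every ratio holds wild-type RNA. The stress median between the groups was 0.0309 as deposited, but 0.243 with arrays centred and scaled and 0.171 with quantile normalization. It thus depended on scaling and did not decide the question.

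For YNR062C, which is PUL3, and YNR064C, both tests stand as chosen only after the result was seen. A single joint limit on both strains was written earlier and decided nothing, and once the values were known it was split by strain and its bounds were changed more than once. A gain of the right end of chromosome XIV as the whole cause would raise neighbouring genes as much. The 11 neighbours had medians of 0.126 in set2Δ and 0.264 on the set2Δsir4Δ arrays, with the highest at 0.90 in either strain. These values lie below both genes of the pair and argue against a gain as the whole cause. Of the 11, 3 were called higher in set2Δ and 6 on the set2Δsir4Δ arrays. The 12 tested subtelomeric genes of that end, YNR064C among them, had a median of -0.24 in set2Δ, with 6 called lower and 3 higher. Those counts and that median argue against a gain of the whole end in set2Δ. On the set2Δsir4Δ arrays the median of the 12 was 0.23. A smaller contribution on those arrays, or from a gain of only the stretch around the pair in either strain, was not excluded. As the bounds were set with the values known, this describes the values and is no independent test. What raised the pair was not tested.

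Whether chance assignment of arrays would give as much was tested by regrouping them, as chosen before the results were seen. Of 35 splits of the 8 arrays 1, the real one, gave as many as 112 differences. The highest other gave 12, in the split that separates the dyes and so has no dye term, and the highest with that term gave 6. As many lists as the 11 past the test came from 10 of 35 splits, with 13 in the highest other, so the number of lists does not set the real grouping apart. The 8 sign patterns of 4 arrays are too few for a share under 0.05, with 1 pattern as large in each group, 1130 calls in set2Δ against 663 in the highest other, which follows the dyes, and 109 in the next, and 1147 on the set2Δsir4Δ arrays against 11.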
